A study of Mus musculus with 20 samples.

How the data were processed

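RNA sequencing libraries of the mouse cell line 416B were compared in 5 groups of 4: Chd7 guides 1, 2 and 3, a Runx1 guide and a control, grouped by the sample titles. Per the labels' protocols, cells with stable Cas9 expression were infected with lentiviruses that carry the guide, harvested after 4 days, sorted at 75 cells into lysis buffer and amplified by Smart-Seq2 with 13 PCR cycles. The deposited table holds whole-number read counts per gene, not normalised. Per the submitters' processing notes, the tools GSNAP (an aligner) and HTSeq (a read counter) and the mouse build mm10 were used, with no version. The annotation release, the strand setting and any filters are not given in the sources used here. Smart-Seq2 does not mark strand, so reads of a gene and of a gene that overlaps it on the opposite strand cannot be told apart, and reads of near-identical copies may be split or lost. The protocol has no molecular identifiers, so counts after 13 PCR cycles are not independent molecules.

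The table has 46172 lines: 46078 mouse genes, 92 ERCC spike-in sequences and 2 vector sequences (Cas9 with blasticidin resistance, and puromycin resistance with BFP). Spike-in and vector sequences, 0.150% to 0.331% of the counts of a library, were left out of library sizes and tests. Ensembl identifiers were given symbols and coordinates from the GENCODE M21 annotation of GRCm38, where 45143 matched and 935 did not. Total gene counts ran from 6697121 to 12724184 per library. At a mean log2 CPM of at least 3 the median SE of a log2 fold change was 0.20 for the Chd7 guides together (12 libraries against 4) and 0.25 for the Runx1 guide (4 against 4). Replicates were compared before averaging: over the 30 pairs within groups the smallest chi-square per degree of freedom against counting error alone was 16.7, so no pair differed by as little as counting error alone would give and each library was counted as 1 sample. This does not bear on the origin of the libraries, and for pairs of different groups the smallest value was 17.0.

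The test was edgeR 4.0.16 (R 4.3.3): TMM factors, filterByExpr on the groups, a quasi-likelihood fit with robust dispersions and 1 coefficient per group over all 20 libraries, and Benjamini-Hochberg adjustment with a threshold of 0.05. Of all genes 12951 were tested. The contrasts were the mean of the 3 Chd7 guides minus control, the Runx1 guide minus control, each Chd7 guide minus control, the Chd7 guides minus the Runx1 guide, and an F test of any difference between the Chd7 guides. Levels are CPM with TMM factors, computed from the deposited counts. Single values were compared by exact two-sided permutation of log2 CPM. Gene sets were 33 lists fixed before the data were examined, of which 29 had at least 5 tested members. They were tested with limma 3.58.1 camera on log2 CPM (prior count 2) with a preset correlation of 0.01, and again with an estimated correlation and with fry, which asks whether the members move 1 way on balance and does not compare them with other genes.

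The lists cover blood cell types (stem and progenitor, neutrophil, monocyte and macrophage, mast cell and basophil, megakaryocyte, erythroid, dendritic, B cell, T and NK), stromal and epithelial and neural crest and neural markers, reported Runx1 targets, CHD family, partners of Runx1 and core binding factor, chromatin remodellers, p53 response, interferon response, MHC class 1, S phase, G2 and M phase, cell cycle inhibitors and D cyclins, ribosome biogenesis, ribosomal proteins, immediate early genes, integrated stress and unfolded protein responses, NF-kB and inflammation, cytokine receptors, integrins and adhesion, phagosome and lysosome, oxidative phosphorylation, mitochondrial DNA, glycolysis and hypoxia, and cholesterol synthesis. Genes named were set by a rule fixed before the data were examined: Chd7 and Runx1; per main comparison up to 12 called genes in each direction, up to 6 for the Chd7 against Runx1 guides, and 6 for differences between Chd7 guides, at a mean log2 CPM of at least 3 and with an established symbol; and up to 4 members of each list with the smallest p in each main comparison, called or not. Other genes named were chosen after their values were seen, as stated or as members called when adjusted over the list alone.

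Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, DESeq2 size factors in edgeR, no filter and a stricter filter on low counts (10 CPM in at least 4 libraries), the replicate number as a block, counts thinned to the smallest library, only the groups of a comparison, each Chd7 guide left out, the library number range as a term, the Runx1 guide against Chd7 guide 2 alone (which share a library number range), and each library left out in turn. Alternatives chosen after seeing the data were removal of the GC content and length trend (lowess, span 0.3, over the 99.6% of tested genes with a value), omission of the 3 libraries that stood apart on the first principal component, and limma-voom with quality weights. Each Chd7 guide was also left out for the Runx1 comparison, and lists were tested with the library number range as a term. The alternatives for Chd7 RNA with guide 2 alone, and the values of Esam against each 2 of the 4 control libraries, were added then as well. Also chosen after seeing the data was a comparison in which genes lowest with Chd7 guide 2 were selected against 2 control libraries and measured against the other 2, in all 6 arrangements, beside 20 simulations of unchanged groups. The pipeline was tested on simulated data with 200 genes changed by known folds over 12951 genes. In the Runx1 comparison 7.46%, 25.4% and 57.6% were found at folds of 1.5, 2 and 4, with 2 of 62 calls wrong, and for the difference between guides 5.97%, 38.8% and 65.2%, with 3 unchanged genes called. For the Chd7 guides 4 of 93 edgeR calls, 12 of 103 limma-voom calls and 21 of 125 DESeq2 calls were of unchanged genes. A list planted at a log2 fold change of 0.30 was called by camera (adjusted p = 5.38e-05) with 0 other lists called, in 29 tested. Genes were simulated independently of each other, so this does not test list calls raised by correlation between genes in the real libraries.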

Results

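RNA was measured in 416B cells, a mouse myeloid progenitor cell line, that stably expressed the nuclease Cas9 and carried a lentiviral guide RNA. The series concerns the chromatin remodeller CHD7 and its relation to the transcription factor Runx1 in the differentiation of blood progenitors. The comparisons ask how targeting either gene altered the transcriptome. There were 5 groups of 4 libraries: 3 different guides against Chd7, 1 guide against Runx1, and a control. The sample titles call the control an empty vector whereas the treatment text describes a guide against GFP, so it is called the control here. Each library was made by Smart-Seq2, a full-length cDNA protocol, from 75 cells sorted into lysis buffer 4 days after infection. Library totals ran from 6697121 counts (Chd7 guide 2, replicate 3) to 12724184 counts (control, replicate 1). The mean per group was 11430000 ± 1498000 in the control, 9423000 ± 2290000 for Chd7 guide 1 and 7616000 ± 821100 for guide 2 (SD, n = 4 each). It was 10700000 ± 819200 for guide 3 and 10360000 ± 1626000 for the Runx1 guide (SD, n = 4 each). The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

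The 4 control libraries lay close together and 3 guide libraries stood apart from the remaining libraries. The first principal component, 16.9% of the variance, placed Chd7 guide 2 replicates 1 and 2 at 76.7 and 72.6 and Chd7 guide 1 replicate 2 at 67.0, whereas the control libraries lay between -22.2 and -14.0. In those 3 libraries GC-rich genes were low relative to the control mean, with a correlation across genes of -0.308, -0.302 and -0.288 between GC content and log2 CPM minus the control mean. Genes are not independent replicates. Runx1 guide replicate 1 had a similar correlation, -0.318, at a score of 17.6. At the opposite end Chd7 guide 1 replicate 1 had a score of -48.6 and a correlation of 0.250. It had 16539 genes with a count and 5.79% of counts from mitochondrial genes. Chd7 guide 2 also had the lowest mean number of genes with a count, 14290 ± 202 against 15520 ± 161 in the control (SD, n = 4 each). The exact two-sided permutation p was 0.0286, the smallest that 4 against 4 libraries can give, and 0.381 when adjusted over the quality measures.

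**Figure D1:**
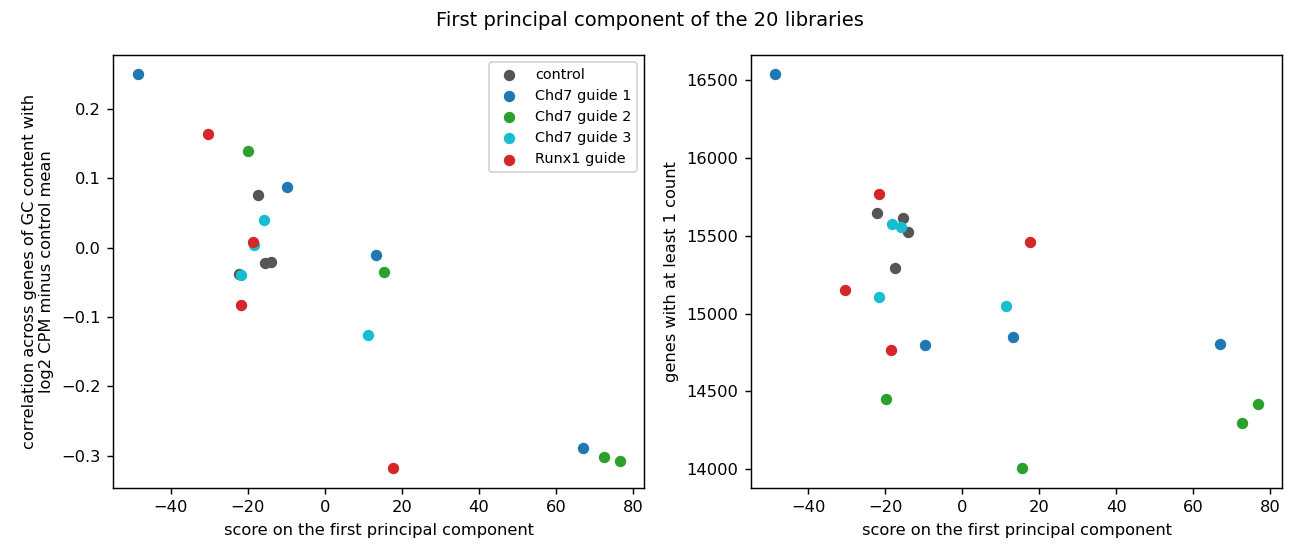
Each point is a library, coloured by group, with its score on the first principal component on the x axis. The y axis is the correlation across genes of GC content with log2 CPM minus the control mean (left) or the number of genes with at least 1 count (right). Chd7 guide 2 replicates 1 and 2 and Chd7 guide 1 replicate 2 lie at the right, with correlations of -0.308, -0.302 and -0.288.

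For neither targeted gene did the RNA level pass the test between the libraries with its guide and the control. Chd7, a chromodomain helicase gene on chromosome 4 at 8690406 to 8867659 of GRCm38 (plus strand), was at 26.1 ± 12.4 CPM (counts scaled to a common library size) in the control, 22.8 ± 8.96 for guide 1, 14.8 ± 4.37 for guide 2 and 20.4 ± 6.17 for guide 3 (SD, n = 4 each). The log2 fold change of Chd7 was -0.45 over the guides (SE 0.27, edgeR adjusted p = 0.799) and -0.82 for guide 2 (SE 0.35, edgeR adjusted p = 0.321). Without control replicate 2, at 42.6 CPM the highest control, these were -0.11 and -0.47, and over the guides it was -0.27 with guide 2 left out and -0.27 with the library number range as a term. Runx1, which encodes a DNA-binding subunit of core binding factor, lies on chromosome 16 at 92601466 to 92826149 of GRCm38 (minus strand) and overlaps Gm26626 on the opposite strand. It was at 57.8 ± 12.7 CPM with its guide and 55.9 ± 4.13 CPM in the control (SD, n = 4 each), a log2 fold change of 0.05 (SE 0.19, edgeR adjusted p = 1.00). Its sign was not settled: the value was -0.11, 0.15 and 0.08 without Runx1 guide replicates 1, 2 and 4, 0.11, 0.00 and 0.03 without control replicates 2, 3 and 4, 0.02 with limma-voom, -0.09 with quality weights and 0.00 with the GC content and length trend removed. Small insertions and deletions at a Cas9 site need not lower the RNA of a gene, so these levels do not measure the efficiency of targeting. The guide sequences and the cut sites were not analysed here.

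With the Chd7 guides, Esam rose and was the gene called over the guides together. Esam encodes an adhesion molecule of endothelial cells, platelets and haematopoietic stem cells, and lies on chromosome 9 at 37528078 to 37538319 of GRCm38 (plus strand). It was at 125.5 ± 11.2 CPM in the control (SD, n = 4), 279.5 ± 11.03 with guide 1, 263.1 ± 21.9 with guide 2 and 244.2 ± 54.5 with guide 3 (SD, n = 4 each). The fold over the guides was 2.09 (log2 fold change 1.06, SE 0.13, edgeR adjusted p = 0.00133). All 16 libraries with a Chd7 or Runx1 guide had more Esam than any control library, the lowest at 163.6 CPM and the highest control at 138.3 CPM. Of 12951 genes tested, Esam was the 1 gene called, and 865 had an unadjusted p under 0.05 where chance gives 647.6. DESeq2 called 17 genes (9 higher and 8 lower) and limma-voom called 2. In simulated libraries of this design the same edgeR test found 10.4% of genes changed by a fold of 1.5, 49.3% at a fold of 2 and 74.2% at a fold of 4. DESeq2 called 125 genes there, of which 21 had not been changed. Over the alternatives the adjusted p of Esam ran from 3.56e-12 to 0.0218. Leaving out Runx1 guide replicate 4 gave 2 calls.

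**Figure D2:**
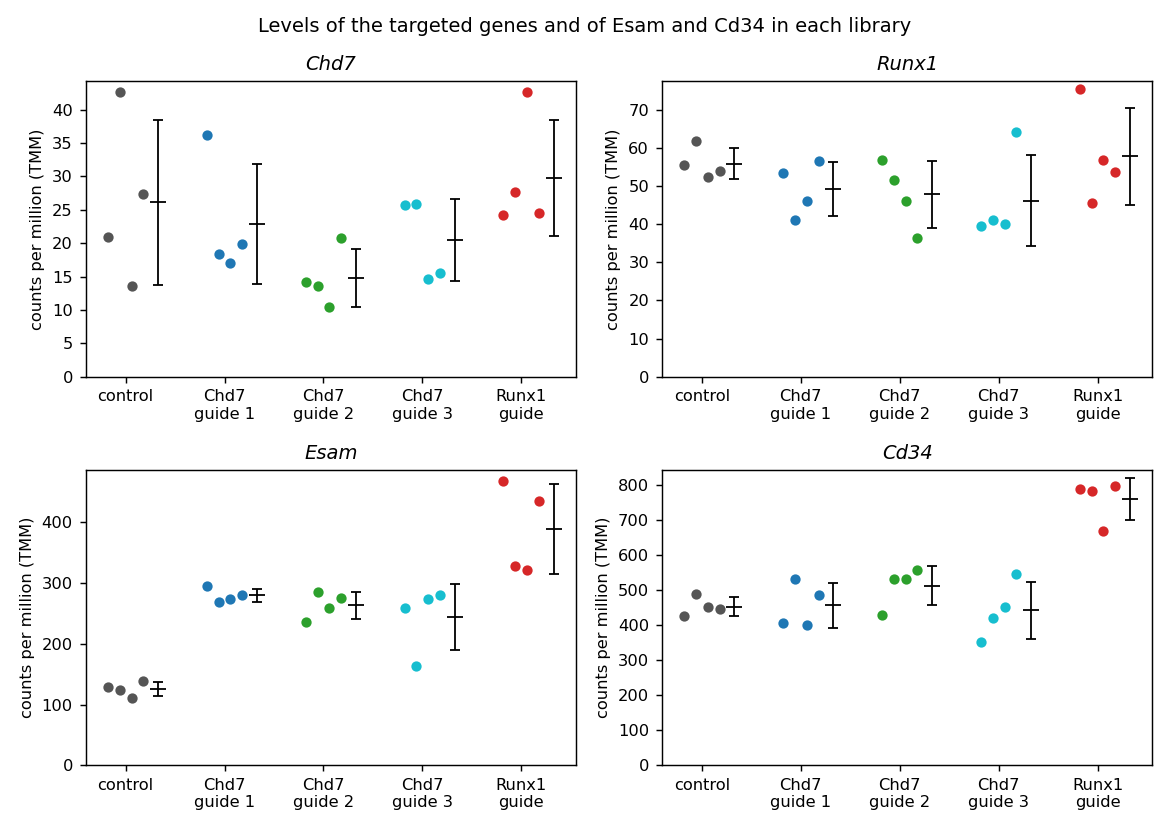
CPM of Chd7, Runx1, Esam and Cd34 on the y axes, with groups on the x axes. Coloured points are the 4 libraries of a group and the black dash and bar beside them are the mean and SD. Esam lies above the highest control library (138.3 CPM) in all 16 guide libraries, and Cd34 averages 759.1 CPM with the Runx1 guide against 453.1 CPM in the control.

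Genes of cholesterol synthesis rose together with the Chd7 guides. All 22 tested members had a positive log2 fold change, with a median of 0.33 (limma camera adjusted p = 4.67e-12), and the call held with an estimated correlation (adjusted p = 0.0322). An example is Sqle, which encodes squalene epoxidase, at 253.8 ± 46.4 CPM (SD, n = 12) against 187.7 ± 11.4 CPM in the control (SD, n = 4). Dhcr7, which encodes the last enzyme of the pathway, was at 126.3 ± 29.0 against 85.7 ± 8.14 CPM. Their log2 fold changes were 0.42 (SE 0.11) and 0.55 (SE 0.14), and those of Cyp51 and Fdft1 were 0.45 (SE 0.15) and 0.46 (SE 0.16), the last 0.28 without the 3 libraries that stood apart. None of the 22 passed edgeR's test over all genes (0 called, 10 with an unadjusted p under 0.05), and 8 were higher when adjusted over the list alone. DESeq2 called Sqle (adjusted p = 0.0482) and Dhcr7 (adjusted p = 0.0485), for each the lowest over the alternatives. The mean of the members was above that of every control library in 12 of 12 Chd7 guide libraries (exact two-sided permutation p = 0.00110).

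Genes of the cell cycle were higher over the Chd7 guides together. For G2 and M phase, 38 of 41 tested members had a positive log2 fold change, with a median of 0.30 (camera adjusted p = 4.24e-12, adjusted p = 0.218 with an estimated correlation). When adjusted over the list alone, 4 were higher: Kif11, Kif20b, Ccna2 and Kif2c. Kif11, which encodes a motor protein of the mitotic spindle, had a log2 fold change of 0.46 (SE 0.12), and Ccna2, the gene of cyclin A2, of 0.43 (SE 0.14). For S phase 34 of 35 were positive, with a median of 0.18 (camera adjusted p = 8.33e-07, adjusted p = 0.320 with an estimated correlation). Tyms, which encodes thymidylate synthase, was at 0.51 (SE 0.16), and none was called when adjusted over the list alone. Subunits of oxidative phosphorylation had a median of 0.22, with 33 of 36 positive (camera adjusted p = 4.32e-06, adjusted p = 0.324 with an estimated correlation). Uqcrq was at 0.42 (SE 0.17), 0.27 with guide 2 left out and 0.64 with guide 3 left out. Ribosomal protein genes, whose reads can be shared with pseudogenes, had a median of 0.17, with 33 of 38 positive (camera adjusted p = 5.31e-04, adjusted p = 0.638 with an estimated correlation). Without the 3 libraries that stood apart the ribosomal protein median was 0.03 and the call was lost (camera adjusted p = 0.308, range over alternatives 2.40e-08 to 0.308). The call was also lost, at a median of 0.12, with the library number range as a term (adjusted p = 0.0692). That median was 0.07 with the GC content and length trend removed and 0.11 without Chd7 guide 1 replicate 2. The median of oxidative phosphorylation was 0.12 without the 3 libraries and 0.14 with the trend removed (camera adjusted p between 1.30e-09 and 0.00220 over the alternatives). The S phase median was 0.10 without control replicate 1 (camera adjusted p = 0.0145, range 2.34e-10 to 0.0145). With guide 3 alone the medians were 0.08 for G2 and M phase (camera adjusted p = 0.0635), 0.04 for oxidative phosphorylation (0.564) and -0.02 for ribosomal proteins, with 14 of 38 positive (0.757), and these lists were called for guides 1 and 2 and not for guide 3.

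Targets of p53 were lower with the Chd7 guides: 17 of 17 tested members had a negative log2 fold change, with a median of -0.34 (camera adjusted p = 4.57e-07, adjusted p = 0.218 with an estimated correlation). Perp, which encodes an apoptosis-related membrane protein, was lower when adjusted over the list alone, at 505.2 ± 68.4 CPM (SD, n = 12) against 629.7 ± 51.9 CPM (SD, n = 4). Phlda3 and Ccng1 had log2 fold changes of -0.60 (SE 0.21) and -0.42 (SE 0.15), the latter -0.28 with guide 1 left out. The p53 mean was below every control library in 11 of 12 Chd7 guide libraries (exact two-sided permutation p = 0.0286). Immediate early genes were lower as a group (18 of 21 negative, median -0.20, camera adjusted p = 0.00212, adjusted p = 0.321 with an estimated correlation). So were genes of NF-kB and inflammation (12 of 16 negative, median -0.43, camera adjusted p = 0.0180, adjusted p = 0.320 with an estimated correlation). Interferon-response genes were also lower (12 of 15 negative, median -0.19, camera adjusted p = 0.0207, adjusted p = 0.320 with an estimated correlation). In these lists none was called when adjusted over the list alone. Examples are Ier5 at -0.98 (SE 0.33), Ptgs2, which encodes cyclooxygenase 2, at -0.86 (SE 0.32), and Oas1a at -0.57 (SE 0.19). The immediate early call was lost without the 3 libraries that stood apart (adjusted p = 0.0560, range over alternatives 4.83e-04 to 0.0560). The NF-kB call was lost without control replicate 1 (adjusted p = 0.0762, range 9.97e-04 to 0.0762) and the interferon call without control replicate 2 (adjusted p = 0.176, range 0.00102 to 0.176). At these losses the medians were -0.15, -0.49 and -0.14, against -0.20, -0.43 and -0.19. The immediate early median was -0.31 without control replicate 1. The interferon median was -0.63 without the 3 libraries and moved to -0.57, -0.40, -0.29, -0.57, -0.33, -0.57 and -0.32 without Chd7 guide 1 replicate 1, guide 2 replicates 1 and 2, guide 3 replicates 1 and 2 and control replicates 3 and 4, in that order. With guide 3 alone 12 of 21 immediate early genes were positive (median 0.04, camera adjusted p = 0.981), as were 8 of 16 genes of NF-kB and inflammation (median -0.11, 0.757). Immediate early genes were called for guides 1 and 2, and the NF-kB and interferon lists for guide 1 only.

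Some groups of blood cell genes were lower over the Chd7 guides together, each of them called for guide 1 and not for guide 2 or 3 alone. Phagosome and lysosome genes were lower (22 of 26 negative, median -0.11, camera adjusted p = 0.0219, adjusted p = 0.218 with an estimated correlation, fry adjusted p = 0.0176). Ncf4, which encodes a subunit of the phagocyte oxidase, was lower when adjusted over the list alone, at 72.5 ± 11.9 CPM (SD, n = 12) against 108.6 ± 17.8 CPM (SD, n = 4). Stem and progenitor genes were lower as a group, though only 10 of 17 were negative (median -0.13, camera adjusted p = 0.0291, adjusted p = 0.321 with an estimated correlation). When adjusted over the list alone, 3 were lower: Spi1 at -0.45 (SE 0.16), which encodes the myeloid factor PU.1, Myb at -0.39 (SE 0.11) and Angpt1 at -0.46 (SE 0.15). Genes reported elsewhere as Runx1 targets were lower as a group (11 of 14 negative, median -0.22, camera adjusted p = 0.0430, adjusted p = 0.218 with an estimated correlation). When adjusted over the list alone, 3 were lower (Spi1, Nfkbia, Tpm1) and 1 was higher (Pf4, which encodes platelet factor 4, at 0.75, SE 0.22). Nfkbia moved from -0.33 to -0.15 with guide 1 left out, -0.57 with guide 3 left out and -0.20 with the library number range as a term, and Tpm1 from -0.28 to -0.18 with guide 2 left out and -0.17 with that term. The phagosome call was lost with the GC content and length trend removed (median -0.07, adjusted p = 0.0693) and without control replicate 4 (median -0.07, adjusted p = 0.269, range over alternatives 0.00135 to 0.269). The stem and progenitor call was lost with that trend removed (median -0.05, adjusted p = 0.0749), and without the 3 libraries that stood apart (median -0.03, adjusted p = 0.105). It was also lost without Chd7 guide 1 replicate 2 (0.0624), Chd7 guide 2 replicate 3 (0.0554), control replicate 1 (0.0750) or control replicate 2 (0.103), each an adjusted p (range 0.0120 to 0.105). The call for reported Runx1 targets was lost with that trend removed (0.0693) and without the 3 libraries that stood apart (0.0888), at a median of -0.21 in both, and with the library number range as a term (median -0.18, 0.0692). It was also lost without Chd7 guide 1 replicates 1 (0.0504) or 2 (0.0673), Chd7 guide 2 replicate 1 (0.0531), Chd7 guide 3 replicates 2 (0.0536) or 4 (0.0621), or control replicates 1 (0.162) or 4 (0.0834), each an adjusted p (range 0.0230 to 0.162). The median of the reported Runx1 targets was -0.12 without control replicate 1 and between -0.25 and -0.20 without the others named. The stem and progenitor median was -0.06 with the library number range as a term, -0.08, -0.09 and -0.20 without Chd7 guide 2 replicates 1, 2 and 4 and -0.08 without control replicate 1.

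Of the 29 lists tested, 12 were called for the Chd7 guides and 17 were not. Markers of other blood cells were among the latter. The median was -0.41 for neutrophil genes (6 tested, camera adjusted p = 0.0930) and -0.27 for monocyte and macrophage genes (12 tested, adjusted p = 0.0930). It was 0.09 for mast cell and basophil genes, whose mean was -0.02 (8 tested, adjusted p = 0.593). It was 0.02 for megakaryocyte genes (17 tested, adjusted p = 0.0807), -0.17 for erythroid genes (10 tested, adjusted p = 0.752) and -0.27 for dendritic cell genes (5 tested, adjusted p = 0.471). Within the megakaryocyte list Ppbp and Pf4, both of platelet granules, were higher when adjusted over the list alone. Ppbp was at 106.0 ± 69.0 CPM (SD, n = 12) against 40.1 ± 16.1 CPM (SD, n = 4). For the remaining lists the median log2 fold change and camera adjusted p follow in that order. They were -0.06 and 0.509 for CHD family genes, -0.10 and 0.240 for partners of Runx1 and core binding factor, and -0.08 and 0.471 for MHC class 1 genes. They were -0.19 and 0.334 for cell cycle inhibitors and D cyclins, 0.05 and 0.514 for ribosome biogenesis, and 0.00 and 0.262 for the integrated stress and unfolded protein responses. They were -0.21 and 0.0736 for cytokine receptors, -0.04 and 0.854 for integrins and adhesion, and 0.03 and 0.890 for genes encoded by mitochondrial DNA. They were 0.01 and 0.509 for glycolysis and hypoxia and -0.07 and 0.471 for chromatin remodellers. Ccnd2, the gene of cyclin D2, was lower and Rbl1 higher when adjusted over the list alone, at log2 fold changes of -0.40 (SE 0.11) and 0.59 (SE 0.18). So was mt-Nd6, lower at -0.48 (SE 0.12). Markers of B cells (1 tested), T and NK cells (4), stromal and epithelial cells (2) and neural crest and neural cells (4) had too few tested members for a test. The exact permutation test of list means, given above for cholesterol and p53, had unadjusted p = 0.033 for interferon and 0.042 for phagosome genes. It was 0.073 for G2 and M phase, 0.064 for S phase, 0.19 for oxidative phosphorylation and 0.38 for ribosomal proteins. It was 0.12 for immediate early, 0.10 for NF-kB, 0.12 for stem and progenitor genes and 0.17 for reported Runx1 targets. For neutrophil genes, not called by camera, it was 0.0071.

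The 3 Chd7 guides shared the rise of Esam, and 7 other genes differed between the guides. Against the control, guide 1 gave 1 called gene (Esam), guide 2 gave 33 (4 higher and 29 lower) and guide 3 gave 1 (Esam). At an unadjusted p under 0.05 there were 832, 1709 and 258 genes, where chance gives 647.6. With guide 2 the genes higher were Esam, Sqle (log2 fold change 0.67, SE 0.13), Kif11 (0.67, SE 0.14) and Mars (0.66, SE 0.13). Mars encodes a transfer RNA synthetase, overlaps Ddit3 on the opposite strand and was chosen after its values were seen. The lower genes had a median of -1.11. Among them was Dapk3, which encodes a protein kinase, at 7.45 ± 2.48 CPM against 31.2 ± 4.18 CPM in the control (SD, n = 4 each). Cited2, which encodes a transcriptional coregulator, was at 148.5 ± 14.7 against 401.5 ± 49.6 CPM, and Hras, a GTPase gene, at 15.5 ± 5.40 against 44.8 ± 11.3 CPM (SD, n = 4 each). With guide 1 Dapk3 and Cited2 were at log2 fold changes of -0.85 (SE 0.25) and -0.66 (SE 0.19), not called, and Hras at 0.10. With guide 3 they were at -0.20, -0.13 and 0.07. Over the guides together edgeR called neither Dapk3 nor Cited2 (adjusted p = 0.175 and 0.189). DESeq2 called Cited2 there (adjusted p = 0.00699) and limma-voom Dapk3 (adjusted p = 0.0313). In the test of a difference between the guides 7 genes passed, each of them lowest with guide 2. They were Srsf2, which encodes a splicing factor (edgeR adjusted p = 0.00553), Arf6 (0.00716), Dapk3 (0.0119), Hras (0.0134), Cited2 (0.0135), Dexi (0.0267) and Alyref (0.0439), the last chosen after its values were seen. Dapk3, Dexi, Arf6 and Srsf2 each overlap a gene on the opposite strand, and no source used here states whether counting used strand.

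Of the 29 genes lower with guide 2, 26 were negative with guide 1 (median -0.37), 21 with guide 3 (median -0.09) and 29 with the Runx1 guide (median -0.43), all against the same control libraries. Unchanged groups simulated against shared controls gave medians of -0.40, -0.40 and -0.42 in that order for the 29 genes lowest with guide 2, with 26.4, 25.8 and 26.4 negative on average. Shared controls can thus give negative signs. How far they did so here is not settled, since the simulation gives each group the same spread, whereas the control libraries were more alike than the guide libraries. For guide 3 the observed median lay outside the simulated range of -0.59 to -0.22. With 29 genes chosen as lowest with guide 2 against 2 control libraries and measured against the other 2, the median was -1.07 with guide 2 (-1.22 to -0.82 over 6 arrangements). The same 4 guide 2 libraries chose and measured these genes, so a negative value for guide 2 was favoured by the choice. In the simulated unchanged groups the 29 genes lowest with guide 2 had a median of -1.13 with guide 2 (-1.53 to -0.81). The size of the guide 2 medians alone thus does not show a change. Against the other 2 control libraries the median of the chosen genes was -0.23 with guide 1 (-0.40 to -0.02), -0.01 with guide 3 (-0.07 to 0.11) and -0.34 with the Runx1 guide (-0.41 to -0.23). Chd7 guide 2 replicates 1 and 2 are among the libraries that stood apart. Without the 3 such libraries guide 2 had 11 calls, of which 6 were among the 33, and 0 genes differed between the guides by edgeR. The 29 genes stayed negative there with a median of -1.15, against -1.11 with all libraries. Of the genes no longer called Hras was at -1.46 (-1.54), Dexi at -1.48 (-1.80) and Srsf2 at -0.47 (-0.60). The genes had been chosen over all 4 guide 2 libraries, which favours such values. The number of libraries alone did not set the calls. With replicates 1 and 2 as the only guide 2 libraries 699 genes were called, and with replicates 3 and 4 it was 1. With all libraries 7 genes differed between the guides, 1107 had an unadjusted p under 0.05 and DESeq2 called 145. The guide 2 count was 7 without guide 2 replicate 1, 14 without replicate 2, and 105 without replicate 4. It was 21 without guide 3 replicates 1, 3 or 4, and 7, 5, 11 and 21 without control replicates 1, 2, 3 and 4. The count between guides was 20 and 15 without guide 1 replicates 1 and 2, and 0, 2, 15 and 1 without guide 2 replicates 1, 2, 3 and 4. DESeq2 called 240 genes for guide 2 (69 higher and 171 lower), and a fit of guide 2 and control alone called 2, with the median of the 29 at -1.10 and all of them negative. The Esam call of guide 3 (adjusted p = 0.0484), and with it the count of genes called for all 3 guides, was lost (0 calls) without any single library except guide 3 replicate 2 and Runx1 guide replicates 1 and 3.

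**Figure D3:**
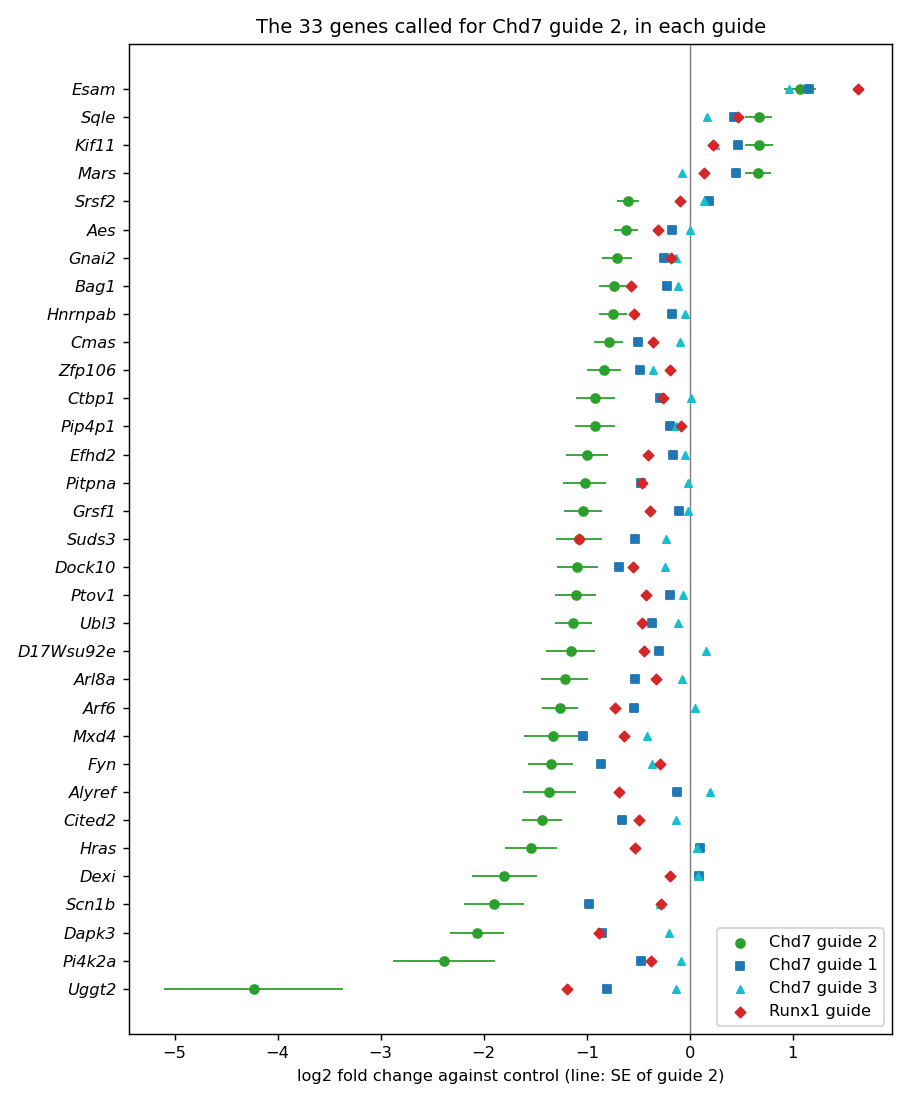
The 33 genes called for Chd7 guide 2, with the log2 fold change against the control on the x axis for each Chd7 guide and the Runx1 guide. The line through each guide 2 point is its SE. The 29 genes lower with guide 2 have a median of -1.11 there, -0.37 with guide 1, -0.09 with guide 3 and -0.43 with the Runx1 guide. Unchanged groups simulated against shared controls had -1.13, -0.40, -0.40 and -0.42 in that order for the 29 genes lowest with guide 2.

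Genes of cholesterol synthesis were called for each Chd7 guide. The median was 0.40 for guide 1 (camera adjusted p = 2.64e-10, adjusted p = 0.0345 with an estimated correlation), 0.48 for guide 2 (1.45e-09 and 0.0811) and 0.15 for guide 3 (2.00e-04 and 0.267). S phase genes had medians of 0.22, 0.26 and 0.17 for guides 1, 2 and 3 (camera adjusted p = 5.29e-05, 2.03e-04 and 2.00e-04). Each was lost with an estimated correlation (adjusted p = 0.368, 0.581 and 0.679). Targets of p53 had medians of -0.47, -0.30 and -0.20 (camera adjusted p = 6.83e-11, 0.00530 and 0.00601). Each was again lost with an estimated correlation (adjusted p = 0.0505, 0.581 and 0.679). The cholesterol median of guide 3 was 0.08 without guide 3 replicate 2 (camera adjusted p = 0.0395, range over alternatives 1.18e-04 to 0.0395). The S phase call of guide 3 was lost, with a median of 0.05, without guide 3 replicate 2 (adjusted p = 0.141) or control replicate 1 (0.204, range 2.39e-08 to 0.204). The S phase median was 0.14 for guide 1 without its replicate 1, and 0.13 for guide 1 and 0.15 for guide 2 without control replicate 1. The p53 call was lost for guide 2 without its replicate 3 (adjusted p = 0.106, range 0.00219 to 0.106). For guide 3 it was lost without its replicates 1 (0.0807) or 4 (0.146) or control replicate 2 (0.0878, range 7.0e-06 to 0.146), and the median was -0.33 without its replicate 3.

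Other lists were called for 1 or 2 of the Chd7 guides, and the difference between guides was not tested for lists. In total 15 lists were called for guide 1, 7 for guide 2 and 5 for guide 3. For guides 1 and 2 the medians were 0.33 and 0.46 for G2 and M phase (camera adjusted p = 3.72e-12 and 2.60e-11) and 0.27 and 0.30 for oxidative phosphorylation (1.92e-05 and 1.35e-06). They were 0.20 and 0.24 for ribosomal proteins (5.35e-04 and 6.21e-06) and -0.32 and -0.25 for immediate early genes (8.33e-05 and 0.00441). With an estimated correlation each of these calls was lost (adjusted p = 0.120, 0.368, 0.626 and 0.200 for guide 1 and 0.581, 0.581, 0.587 and 0.581 for guide 2). For guide 1 alone the phagosome and lysosome list was called with the preset (median -0.19, camera adjusted p = 5.35e-04) and with an estimated correlation (0.0345). Also called for guide 1 alone were interferon response (median -0.36, camera adjusted p = 1.30e-04), NF-kB and inflammation (-0.79, 1.53e-04), reported Runx1 targets (-0.33, 0.00203) and stem and progenitor genes (-0.07, 0.00627). Each of these 4 was lost with an estimated correlation (adjusted p = 0.109, 0.120, 0.0505 and 0.213). Without Chd7 guide 1 replicate 2 the ribosomal protein median of guide 1 was 0.02 (adjusted p = 0.953, range 5.55e-12 to 0.953), its oxidative phosphorylation median 0.14 and its stem and progenitor median -0.04 (adjusted p = 0.0843, range 9.48e-04 to 0.0843). Without guide 1 replicate 1 the medians of guide 1 were 0.34 for ribosomal proteins, -0.51 for immediate early genes and -0.30 for stem and progenitor genes. Without the 3 libraries that stood apart the medians of guide 2 were 0.26 for G2 and M phase, 0.13 for oxidative phosphorylation and 0.12 for ribosomal proteins, and those of guide 1 were 0.13 for oxidative phosphorylation and -6.89e-04 for ribosomal proteins (adjusted p = 0.919), the latter no longer called. With the GC content and length trend removed the medians were 0.20 for oxidative phosphorylation with guide 2, and 0.08 and 0.12 for ribosomal proteins with guides 1 and 2. The immediate early call of guide 2 was lost without its replicate 1 (adjusted p = 0.0571) and without the 3 libraries that stood apart (median -0.15, 0.295, range 0.00177 to 0.295), and the median was -0.68 without its replicate 4 and -0.42 without control replicate 1. The interferon median of guide 1 lay between -0.84 and -0.54 without any single library except Runx1 guide replicate 3 and control replicate 2.

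With the Runx1 guide Esam rose to 388.1 ± 74.2 CPM (SD, n = 4), a fold of 3.09 over the control (log2 fold change 1.63, SE 0.15, edgeR adjusted p = 1.64e-05, higher in 4 of 4 libraries). It was the 1 gene called. There were 481 genes with an unadjusted p under 0.05, fewer than the 647.6 that chance gives. DESeq2 called 23 (7 higher and 16 lower) and limma-voom 2. Cd34, which encodes a surface marker of progenitors, lies on chromosome 1 at 194938819 to 194961279 of GRCm38 (plus strand) and overlaps Gm16897 on the opposite strand. It was at 759.1 ± 60.5 CPM against 453.1 ± 26.1 CPM in the control (SD, n = 4 each, log2 fold change 0.74, SE 0.13, edgeR adjusted p = 0.0695). Cd34 passed with DESeq2 (1.66e-04), limma-voom (0.0228), no filter on low counts (0.0410), a fit of the Runx1 guide and control alone (0.0232), with the replicate block (0.0252), with quality weights (0.00289), without the 3 libraries that stood apart (0.0472) and with Chd7 guide 1 left out of the fit (0.0396). It also passed without Chd7 guide 3 replicate 1 (0.0340) or 4 (0.0280) and without Runx1 guide replicate 3 (0.0484), each an adjusted p. Its adjusted p was 0.752 with the library number range as a term. The log2 fold change of Cd34 was 0.55 with that term and between 0.71 and 0.80 in the other alternatives. The count was 2 without Chd7 guide 3 replicate 1 or 4, 3 without Runx1 guide replicate 3 and 4 with Chd7 guide 1 left out of the fit.

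Cholesterol synthesis genes rose with the Runx1 guide, with 20 of 22 positive (median 0.28, camera adjusted p = 6.73e-07, adjusted p = 0.110 with an estimated correlation). Sqle (0.46, SE 0.13) and Insig1 (0.65, SE 0.19), a feedback regulator of sterol synthesis, were higher when adjusted over the list alone. With the library number range as a term the list median was 0.09 and the call was lost (adjusted p = 0.373, range over alternatives 1.59e-07 to 0.373), and Sqle was at 0.09 (over all genes adjusted p = 0.978, range 0.0741 to 1.00). That fit takes the 3 Chd7 guides to act alike. The mean of the list was above every control library in 4 of 4 Runx1 guide libraries. Glycolysis and hypoxia genes were higher, with 20 of 23 positive (median 0.25, camera adjusted p = 1.66e-04, adjusted p = 0.639 with an estimated correlation). When adjusted over the list alone Pdk1, which encodes a kinase of pyruvate dehydrogenase, was higher, at 187.8 ± 40.9 CPM against 113.1 ± 7.72 CPM (SD, n = 4 each). So was Slc2a1, which encodes a glucose transporter, at 228.8 ± 125.3 against 117.2 ± 11.7 CPM, with a log2 fold change of 0.96 that was 0.56 without Runx1 guide replicate 3. Megakaryocyte genes were higher, with 13 of 17 positive (median 0.21, camera adjusted p = 0.00198, adjusted p = 0.110 with an estimated correlation). Treml1 (0.91, SE 0.24), Rab27b (0.74, SE 0.23) and Ppbp (1.36, SE 0.42) were higher when adjusted over the list alone. Targets of p53 were lower, with 14 of 17 negative (median -0.31, camera adjusted p = 1.06e-04, adjusted p = 0.442 with an estimated correlation). The apoptosis gene Bax was lower when adjusted over the list alone, at 227.5 ± 27.8 against 323.6 ± 22.03 CPM (SD, n = 4 each). Genes of the integrated stress and unfolded protein responses had a median of 0.13, with 22 of 24 positive (camera adjusted p = 0.0497, adjusted p = 0.706 with an estimated correlation). The glycolysis call was lost without Runx1 guide replicate 3 (adjusted p = 0.243, range over alternatives 2.93e-08 to 0.243). The stress response call was lost with DESeq2 size factors (adjusted p = 0.0502), and without the 3 libraries that stood apart (0.109). It was also lost without any single library except Runx1 guide replicates 1 and 4 and control replicates 1 and 4, with an adjusted p of up to 0.607. With the library number range as a term the megakaryocyte call was lost at a median of 0.21 (adjusted p = 0.0546, range 1.53e-04 to 0.0546) and the stress response call at a median of 0.08 (0.559). Medians also moved without single libraries. The megakaryocyte median was 0.14 and 0.13 without Runx1 guide replicates 2 and 4 and 0.33 without control replicate 2. The p53 median was -0.20 without Runx1 guide replicate 1 and -0.17 without control replicate 2. The stress response median was 0.20, 0.03 and 0.20 without Runx1 guide replicates 1, 3 and 4 and 0.07 without control replicate 2, and the glycolysis median was 0.12 without Runx1 guide replicate 3.

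**Figure D4:**
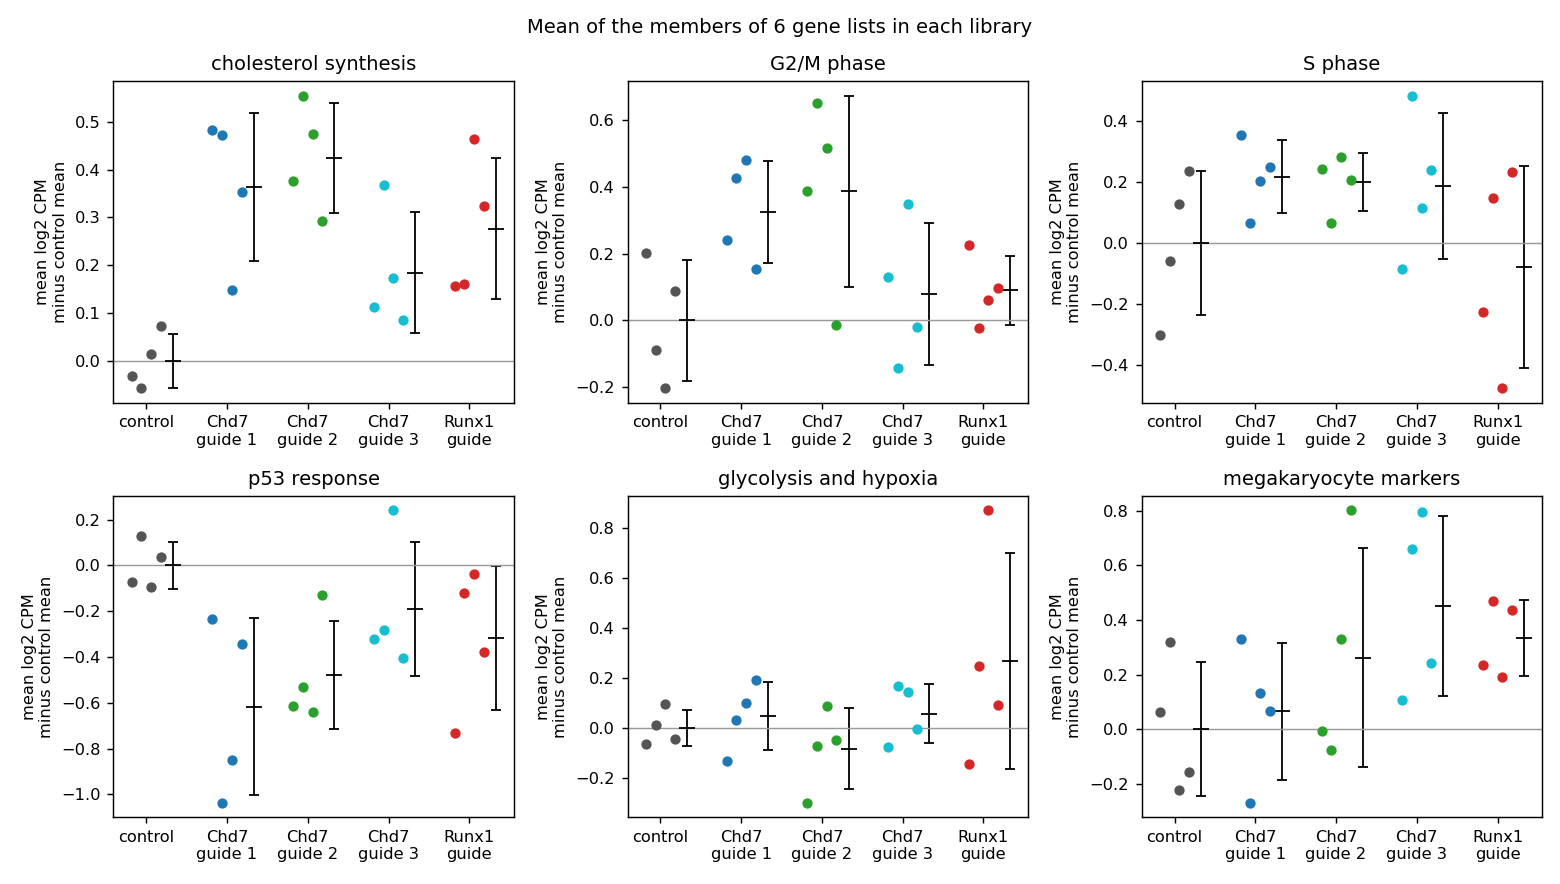
The mean over the members of 6 gene lists of log2 CPM minus the control mean (y axes) in each library (coloured points), by group (x axes). The black dash and bar are the mean and SD of the 4 libraries. Cholesterol synthesis is above every control library in 12 of 12 Chd7 guide and 4 of 4 Runx1 guide libraries.

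Among lists not called for the Runx1 guide, the stem and progenitor list had members on both sides. Kit (-0.62, SE 0.21, and -0.34 with the library number range as a term) and Myb (-0.54, SE 0.14) were lower and Cd34 higher when adjusted over the list alone, around a median of 0.00 (camera adjusted p = 0.809). Dendritic cell genes had a median of 0.60 (5 tested, 5 positive, adjusted p = 0.0560) and G2 and M phase genes of 0.09 (30 of 41 positive, adjusted p = 0.0560). S phase genes had a median of -0.03 (adjusted p = 0.296), and reported Runx1 targets of -0.07 with 6 of 14 positive (adjusted p = 0.950). For partners of Runx1, ribosome biogenesis, immediate early genes, cytokine receptors and oxidative phosphorylation the median and the camera direction differed in sign, with adjusted p between 0.322 and 0.999.

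Between the Chd7 and Runx1 guides, Cd34 was the gene called, at 470.2 ± 68.9 CPM with the Chd7 guides (SD, n = 12) against 759.1 ± 60.5 CPM with the Runx1 guide (SD, n = 4). The log2 fold change was -0.69 (SE 0.10, edgeR adjusted p = 0.0127). Esam was lower with the Chd7 guides by a log2 fold change of -0.57 (SE 0.12) that did not pass in edgeR (adjusted p = 0.197) and passed in DESeq2 (adjusted p = 0.0117). Over all genes 1 was called, 1055 had an unadjusted p under 0.05, DESeq2 called 47 and limma-voom 8. The Cd34 call was lost in a fit of the groups compared alone (log2 fold change -0.69, adjusted p = 0.101), with Chd7 guide 1 (-0.66, 0.0775) or guide 3 (-0.65, 0.0666) left out and with the library number range as a term (-0.57, 0.161). It was also lost without Runx1 guide replicate 1 (-0.68, 0.0585), 2 (-0.68, 0.138) or 4 (-0.67, 0.0605), and the adjusted p ranged from 2.58e-06 to 0.161 over the alternatives. The library numbers of Chd7 guides 1 and 3 and the control lie in a different range from those of Chd7 guide 2 and the Runx1 guide, which the labels do not call a batch. The count was 3 without Chd7 guide 1 replicate 1, 2 without guide 2 replicate 1 or guide 3 replicate 1, 4 without guide 2 replicate 3 or 4, and 0 without Runx1 guide replicate 1, 2 or 4.

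By list, S phase genes (34 of 35 positive, median 0.26, camera adjusted p = 8.54e-10) and G2 and M phase genes (36 of 41, 0.22, 2.08e-05) were higher with the Chd7 guides than with the Runx1 guide. So were ribosomal proteins (37 of 38, median 0.20, camera adjusted p = 6.40e-06) and oxidative phosphorylation (30 of 36, 0.20, 2.08e-05). Glycolysis and hypoxia genes (19 of 23 negative, median -0.25, camera adjusted p = 0.00164) and dendritic cell genes (5 of 5, -0.87, 0.00622) were lower. So were stem and progenitor genes (14 of 17 negative, median -0.15, camera adjusted p = 0.0153) and NF-kB and inflammation genes (12 of 16, -0.37, 0.0436). None of these 8 calls held with an estimated correlation, with adjusted p = 0.462 for each of them except ribosomal proteins (adjusted p = 0.563). Cholesterol synthesis was not called (median 0.10, adjusted p = 0.265), nor was the p53 list (median -0.09, adjusted p = 0.593). The glycolysis call was lost without Runx1 guide replicate 3 (adjusted p = 0.536) and the stem and progenitor call without that library (0.0867) or Chd7 guide 1 replicate 2 (0.0560). The dendritic call was lost without any single library except Chd7 guide 1 replicate 1, guide 2 replicates 2 and 3, guide 3 replicate 1, Runx1 guide replicate 3 and control replicate 1 (adjusted p up to 0.130). The NF-kB call was lost without any except guide 1 replicate 1, guide 3 replicate 1, Runx1 guide replicates 1 and 4 and control replicate 1 (up to 0.536). Without the 3 libraries that stood apart the dendritic (median -0.77, 0.0919), NF-kB (-0.13, 0.230) and stem and progenitor (-0.04, 0.131) calls were lost, and the ribosomal protein median was 0.11. With the GC content and length trend removed the ribosomal protein (median 0.08, 0.0533), NF-kB (-0.42, 0.0594) and stem and progenitor (-0.12, 0.0647) calls were lost, and the oxidative phosphorylation median was 0.10. With the library number range as a term the dendritic (-1.14, 0.0754) and NF-kB (-0.46, 0.219) calls were lost, each second value an adjusted p, and the medians of G2 and M phase, glycolysis and stem and progenitor genes were 0.37, -0.38 and -0.26. Without Runx1 guide replicate 3 the S phase median was 0.12 and the glycolysis median -0.10. Without Runx1 guide replicate 1 the oxidative phosphorylation median was 0.31 and the dendritic median -0.53. The dendritic median was -0.57 without Chd7 guide 3 replicate 2, and the stem and progenitor median -0.08 without Chd7 guide 2 replicate 2.

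Esam was the gene called both for the Chd7 guides and for the Runx1 guide. Independent lists of these sizes would share 7.7e-05 genes and simulated unchanged groups against shared controls shared 0 over 20 simulations. Groups simulated as unchanged are bound to have few calls to share. Neither figure allows for a control culture that differs in Esam, so neither tests a shared effect of the targets. With the controls split between the comparisons, 2 for each, Esam kept its log2 fold change, at 0.97 to 1.16 for the Chd7 guides and 1.54 to 1.72 for the Runx1 guide. It was called for the Runx1 guide in all 6 arrangements and for the Chd7 guides in 0 by edgeR (adjusted p = 0.0539 to 0.399), and with the fold change kept and fewer control libraries this loss does not speak against a shared change. Log2 fold changes of the Chd7 and Runx1 comparisons correlated at 0.457 across 9131 genes, which are not independent replicates, where unchanged groups simulated against shared controls correlated at 0.610. Their covariance was 0.0334 against 0.0501 simulated, a difference of -0.0167, and it was 0.00707 when the controls were split (0.00137 to 0.0141 over 6 arrangements). The SE of the covariance, from leaving out each of the 20 libraries in turn (jackknife), was 0.0187. The difference is smaller than this SE, and the range over arrangements does not measure the spread between libraries. The simulation gives each group the same spread, whereas the control libraries were more alike than the guide libraries. For Chd7 guides 1 and 2 the covariance with split controls was 0.0442, and 0.0319 without the 3 libraries that stood apart. For guides 1 and 3 it was 0.0111, and 0.00526 without the 3 libraries. For guides 2 and 3 it was 0.00933 (-2.06e-05 to 0.0161 over 6 arrangements), and 0.00562 without the 3 libraries (-0.00361 to 0.0116).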

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

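The tests with the GC content and length trend removed, without the 3 libraries that stood apart, of guide 2 replicates against each other, of the control range and of lists with the library number range as a term were chosen after the calls were seen, and the last of the guide 2 replicate tests after the first of them, whereas the splits of the samples were planned.

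The 33 genes called for Chd7 guide 2 and the 7 that differ between guides, with adjusted p of 0.00553 (Srsf2), 0.00716 (Arf6), 0.0119 (Dapk3), 0.0134 (Hras), 0.0135 (Cited2), 0.0267 (Dexi) and 0.0439 (Alyref), rest on a group in which replicates 1 and 2 stood apart. Removing the GC content and length trend left 26 of the 33 called, which argues against that trend as the whole cause. The lower genes differed from the control in replicates 3 and 4 at 0.995 of the difference in replicates 1 and 2, which met the bound set in advance against those 2 libraries as the cause, but the genes had been called over all 4 libraries, which favours genes alike in all 4, so that bound was wrong and this value does not decide. With 339 genes chosen from replicates 1 and 2 alone the ratio was 0.104 (-1.43 against -0.15), as library-specific differences or regression to the mean would give, while 53 genes chosen from replicates 3 and 4 gave 0.417. With replicates 1 and 2 as the only guide 2 libraries the fit called 699 genes, and with replicates 3 and 4 it called 1. The large count thus came with the 2 libraries that stood apart, and part or much of what guide 2 calls may be specific to them. No other split of the 8 guide 2 and control libraries called a gene (1 of 35 splits, the real split, gave 33, highest other 0). That is the lowest share 35 splits can give. Between guides, 2 of 100 splits gave 7 or more genes (highest other 604, in a split with all 3 libraries that stood apart under 1 guide, which points to a structure of the samples). A random grouping thus rarely gave as many. The library numbers of guide 2 and the Runx1 guide lie in a different range from those of the control and guides 1 and 3. Against control libraries not used to choose them, the genes lowest with guide 2 had a median of -0.34 with the Runx1 guide. It was -0.23 with guide 1 and -0.01 with guide 3. An effect of guide 2, on or off its target, and a difference between the ranges cannot be told apart and stay untested.

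The log2 fold change of Esam with the Chd7 guides was 1.08 with the GC content and length trend removed, which argues against that trend. If the control libraries stood apart for many genes, whatever the guide, Esam could follow from them: 8 genes had control values outside the range of the 16 guide libraries, against a median of 3 and a highest of 24 over 100 random choices of 4 libraries, which leaves this open. A change common to active guides, a difference between the control culture and the others, and an effect of both targets on Esam cannot be told apart, since every guide shared the same 4 control libraries. The 1 call was reached in 6 of 100 splits for the Chd7 guides (highest other 1927, so chance is not excluded by the count alone, and the 2 splits with over 10 calls held all 3 libraries that stood apart in the group of 4, which points to a structure of the samples), in 2 of 35 for guide 1 (highest other 1, chance not excluded), in 1 of 35 for guide 3 (highest other 0), in 2 of 100 for all 3 guides (1 real, highest other 13) and in 1 of 35 for the Runx1 guide (highest other 0). In the last 3 a random grouping rarely gave as many. However, 1 of 35 is the lowest share 35 splits can give, with no adjustment over the split tests. The guide 3 call (edgeR adjusted p = 0.0484) was lost with limma-voom and without most single libraries, so chance stays open for it.

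The median of the cholesterol list was 0.36 with the GC content and length trend removed and 0.34 without the 3 libraries that stood apart, which argues against both as its cause. Its mean was as large in 1 of 100 splits for the Chd7 guides (mean 0.34, highest other 0.32) and 1 of 35 for the Runx1 guide (0.29, highest other 0.25), each the real split. A random grouping thus rarely moved this list as far, though the highest other mean was close for the Chd7 guides. The splits followed this list alone and not the list that moved most in each. They do not exclude chance for the cholesterol list as 1 of 29 tested. With the library number range as a term the median was 0.29 for the Chd7 guides (adjusted p = 3.65e-09) and 0.09 for the Runx1 guide (adjusted p = 0.373) in a fit that takes the Chd7 guides to act alike, so a difference between the number ranges stays open for the Runx1 guide. An effect of the guides through their targets and a difference between the control culture and the others stay open and untested. For counts of lists, 12 or more were called in 3 of 100 splits for the Chd7 guides (highest other 15, so rarely as many), 5 or more in 15 of 35 for the Runx1 guide (highest other 9, chance not excluded) and 8 or more in 17 of 100 between the Chd7 and Runx1 guides (highest other 12, chance not excluded).

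Differences between the Chd7 and Runx1 guides that passed their test were Cd34 (adjusted p = 0.0127), whose count of 1 call was reached in 12 of 100 splits (highest other 1987, so chance is not excluded; of the 6 splits with over 10 calls 2 had all 3 libraries that stood apart in the group of 4 and 3 had 0 of them, with up to 218 calls, so a structure of the samples other than those libraries is not ruled out), and the lists of S phase (8.54e-10), ribosomal proteins (6.40e-06), G2 and M phase and oxidative phosphorylation (2.08e-05 each), glycolysis and hypoxia (0.00164), dendritic cells (0.00622), stem and progenitor cells (0.0153) and NF-kB and inflammation (0.0436), each a camera adjusted p. None of these 8 lists was called with an estimated correlation (adjusted p = 0.563 for ribosomal proteins and 0.462 for each of the others) or with fry.

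A single library lay far from the other 3 of its group in 21 of 340 groups tested, where chance flags about 1 in 20 groups, or 17. Chd7 guide 1 replicate 1 had 16539 genes with a count, and in it Chd7 was at 36.2, Dhcr7 at 153.6, Kit at 140.3 and Pdk1 at 96.5 CPM. Chd7 guide 1 replicate 2 had Fdft1 at 156.4 CPM. Chd7 guide 2 replicate 2 had Arf6 at 46.0 CPM, and replicate 4 had Ccna2 at 291.4 and Uggt2 at 0.762 CPM. Chd7 guide 3 replicate 2 had 10.1% of counts from mitochondrial genes and mt-Nd6 at 311.3 CPM, and replicate 4 had Runx1 at 64.1, Ier5 at 13.6 and Dusp5 at 24.3 CPM. Runx1 guide replicate 1 had Ccna2 at 451.5 and Uggt2 at 1.27 CPM, and replicate 3 had Cd34 at 668.9 CPM. Among the controls Fdft1 was at 103.2 CPM in replicate 1, Zmat3 at 70.0 and Srsf2 at 409.3 CPM in replicate 2, and Kif11 at 92.6 CPM in replicate 3. Uggt2 was chosen after its values were seen.

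In data outside the comparisons, spike-in sequences averaged 0.0210% of counts with Chd7 guide 2 and 0.0150% with the Runx1 guide, above the highest control library (0.0144%; control mean 0.0110%), but 2 of 4 libraries of each lay below that library and neither difference passed its test (exact two-sided permutation p = 0.0857 and 0.371, adjusted p = 0.508 and 0.714 over the quality measures).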

How the results depend on the processing

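The alternatives with the GC content and length trend removed, without the 3 libraries that stood apart, with quality weights, of the Runx1 guide with a Chd7 guide left out and of lists with the library number range as a term were chosen after the results were seen; the others were planned. The 1 result past its threshold that changed direction was the ribosomal protein list of Chd7 guide 1, with a median of -6.89e-04 (adjusted p = 0.919) without the 3 libraries, and the cause of each move was not tested unless stated. Counts of called genes were, for the Chd7 guides (1), 17 with DESeq2, 2 with limma-voom, with no filter and with only the groups compared, 3 with guide 3 left out and 10 with quality weights; for the Runx1 guide (1), 23 with DESeq2, 2 with limma-voom, with no filter and without the 3 libraries, 3 with only the groups compared, 9 with quality weights, 4 with Chd7 guide 1 left out and 0 against Chd7 guide 2 in place of the control; for guide 1 (1), 20 with DESeq2, 2 without the 3 libraries and 3 with quality weights; for guide 2 (33), 240 with DESeq2, 19 with limma-voom, 2 with only the groups compared (fewer samples) and 11 without the 3 libraries; for guide 3 (1), 4 with DESeq2 and 0 with limma-voom, with only the groups compared and without the 3 libraries. Genes called for all 3 guides (1) were 0 with limma-voom, with only the groups compared and without the 3 libraries. Genes that differed between Chd7 guides (7) were 145 with DESeq2, 11 when thinned, 12 with the trend removed and 0 without the 3 libraries. Genes that differed between the Chd7 and Runx1 guides (1) were 47 with DESeq2, 8 with limma-voom, 4 with no filter, 2 with a stricter filter, when thinned, with guide 2 left out and without the 3 libraries, 17 with quality weights, and 0 with only the groups compared, with guide 1 or guide 3 left out and with the library number range as a term. Genes shared by the Chd7 and Runx1 calls (1) were 2 with DESeq2. Lists called were 1 with an estimated correlation and 2 with fry for the Chd7 guides (12), 0 with either for the Runx1 guide (5), 5 with the trend removed and 0 with an estimated correlation or fry between them (8), 2 with an estimated correlation and 5 with fry for guide 1 (15), 0 and 1 for guide 2 (7), and 0 with either for guide 3 (5).

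With each library left out in turn the counts ran from 1 to 2 for the Chd7 guides, 1 to 3 for the Runx1 guide, 1 to 2 for guide 1, 5 to 105 for guide 2, 0 to 1 for guide 3 and for all 3 guides, 0 to 20 between Chd7 guides and 0 to 4 between the Chd7 and Runx1 guides, and lists from 9 to 13, 4 to 7 and 5 to 10, and 12 to 15, 6 to 8 and 4 to 7 for guides 1, 2 and 3. The log2 fold change of Esam ran from 1.01 to 1.11 for the Chd7 guides and 1.52 to 1.71 for the Runx1 guide over the 35 alternatives of each comparison with the control and passed in each of these; Chd7 and Runx1 RNA passed in none. Whether replicate numbers pair the samples was not settled. Over 40 pairs of libraries with the same number the correlation of their deviations ran from -0.47 to 0.35 (median 0.04), and 12 were over 0.1. Over 120 pairs with different numbers the median was -0.02. Of 20 libraries 9 correlated best with their own number among the 4 replicate numbers. With the replicate block the Runx1 guide had 2 called genes and guide 3 and all 3 guides had 0; it ended the stress response call of the Runx1 guide (adjusted p = 0.0584), and Cd34 passed for the Runx1 guide (adjusted p = 0.0252). With counts thinned to the smallest library no count of called genes fell: the 11 between Chd7 guides held all 7, and 30 of the 33 called for guide 2 were the same genes. Lower depths were not tried.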

Other observations

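The comparison of the vector transcript with the libraries that stood apart was made after their values were seen, and no test was planned for it.

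The transcript of the lentiviral vector (puromycin resistance with BFP) was lowest in the 3 libraries that stood apart, at 1047 and 1212 CPM in Chd7 guide 2 replicates 1 and 2 and 1638 CPM in Chd7 guide 1 replicate 2, followed by 1720 CPM in Runx1 guide replicate 1. The control averaged 2371 ± 134 CPM (SD, n = 4), and Chd7 guide 2 as a group 1686 ± 657 CPM (SD, n = 4; exact two-sided permutation p = 0.114; adjusted p = 0.508 over the quality measures). The Cas9 transcript averaged 179.7 ± 19.2 CPM in the control, 159.7 ± 42.9 CPM with Chd7 guide 2 and 198.8 ± 11.8 CPM with the Runx1 guide. The lowest quality weight that limma gave was 0.383, in Chd7 guide 1 replicate 2, and the weights of the 4 control libraries lay between 1.28 and 1.46. Low weights did not single out the libraries that stood apart. Chd7 guide 2 replicates 1 and 2 had 0.650 and 0.841. Chd7 guide 1 replicate 1 (0.438), Runx1 guide replicate 1 (0.503) and Chd7 guide 2 replicate 4 (0.640) had less.

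Of the lists not called for the Chd7 guides together, 4 were called for single guides. Monocyte and macrophage genes were lower with guide 1 (median -0.25, camera adjusted p = 0.0340, adjusted p = 0.171 with an estimated correlation) and guide 3 (median -0.36, camera adjusted p = 0.0455, adjusted p = 0.267 with an estimated correlation). Neutrophil genes (median -0.58, camera adjusted p = 0.0340, adjusted p = 0.120 with an estimated correlation) and cytokine receptors (median -0.26, camera adjusted p = 8.57e-04, adjusted p = 0.120 with an estimated correlation) were lower with guide 1. Megakaryocyte genes were higher with guide 3 (median 0.16, camera adjusted p = 6.84e-04, adjusted p = 0.0578 with an estimated correlation). The monocyte and macrophage call of guide 1 was lost without guide 1 replicates 1 (adjusted p = 0.184) or 4 (0.0778) or control replicates 3 (0.0840) or 4 (0.169, range over alternatives 0.00457 to 0.184). That of guide 3 was lost without the 3 libraries that stood apart (0.0648), guide 2 replicate 3 (0.0510), guide 3 replicates 2 (0.141, median -0.23) or 4 (0.171) or control replicates 3 (0.114) or 4 (0.268, median -0.22, range 0.00529 to 0.268). The neutrophil call was lost without the 3 libraries (0.0706) and without any single library except Chd7 guide 3 replicate 3, Runx1 guide replicate 2 and control replicate 2 (up to 0.165, range 0.0205 to 0.165). The cytokine receptor call was lost without the 3 libraries (0.0706) and without guide 1 replicate 2 (0.0788, median -0.11, range 2.90e-04 to 0.0788). The megakaryocyte median was 0.25 and 0.10 without guide 3 replicates 1 and 3 and 0.24 and 0.34 without control replicates 1 and 2. The difference between guides was not tested for these lists.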
